A study of Homo sapiens with 20 samples.

How the data were processed

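Messenger RNA was sequenced from 3 lung adenocarcinoma cell lines, HCC827, H23 and A549, in 20 libraries that form 10 groups of 2. In the GSK-J4 experiment (12 libraries, all 3 lines), cells received the solvent DMSO or 10 µM GSK-J4 for 24 h, per the labels. In the siRNA experiment (8 libraries, A549 and H23), cells received siNT, taken here as the control siRNA, or siKDM6B. Per the labels' protocols, libraries came from a stranded poly(A) mRNA kit and were read on a NextSeq instrument.

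The deposited table gives RPKM (reads scaled by transcript length and by the mapped reads of the library) for 11568 genes, and the authors computed these values before deposit. The submitters' processing notes name TopHat and the human build hg19, without versions and without saying how reads on shared or overlapping genes were counted. Genes with near-identical copies, readthrough transcripts and overlapping genes are therefore uncertain. The table holds no counts, and its low values show no steps of whole reads, so the depth of each library and the counting error of each value are unknown. The sum of RPKM over the listed genes ran from 368432 to 421015 in the GSK-J4 experiment and from 216167 to 302065 in the siRNA experiment. The lowest listed value is 0.1, here called the floor. In the siRNA experiment 90 genes stood at the floor in both libraries of an arm of a line while the other arm of that line averaged at least 1 RPKM, against 4 genes in the GSK-J4 experiment. For such genes the RPKM of each library is given and no fold.

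Tests were run in R 4.3.3 with limma 3.58.1 on log2(RPKM + 1), the pseudocount being 1, with an intensity trend in the empirical Bayes step. Genes with at least 1 RPKM in at least 2 libraries of the experiment were tested, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. All tests were two-sided. Each experiment was fitted apart with a mean per group; differences between the effects of the compound and of the knockdown were fitted on all 20 libraries. A fold change is on the log2(RPKM + 1) scale and understates the change of genes with low values. The p-values measure the spread between the 2 libraries of a group, pooled over all groups of a fit. That spread may hold technical variation only. Groups are given as mean ± SD with n = 2, and changes with their standard error (SE).

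The named genes follow a fixed rule. KDM6A and KDM6B are always named. For the effects averaged over lines, the rule takes the 10 rising and 10 falling called genes with the largest change among those that moved the same way in each line. For each other comparison it takes the 5 rising and 5 falling called genes with the largest change, and for each described list up to 4 members with the smallest p. Some genes that the rule takes are not reported here, though they stay in every fit and count. In all, 33 gene lists for pathways, cell types and RNA quality were fixed. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. The tests, the lists, the naming rule and most alternatives were chosen before the data were examined. Which lists to describe for each comparison was decided after their values were seen.

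Alternatives were a pseudocount of 0.1, no filter (every gene above the floor in at least 1 library), quantile normalization, rescaling by median ratios, all 20 libraries in a joint fit, only the 4 libraries of a comparison, an additive fit of line and treatment, a replicate block, and each library left out in turn. Where a library was left out, its group's remaining library was assumed to vary like the other groups. Chosen after seeing the data were a test without the genes at the floor in a whole arm, a replicate block within each line, and that block with removal of each library's trend with GC content and transcript length for the lists. Replicate numbers come from the labels. The deviations of same-numbered control and treated libraries from their group means correlated across genes at 0.50 in HCC827, 0.34 in H23 and 0.28 in A549 of the GSK-J4 experiment. In the siRNA experiment the values were 0.60 in A549 and 0.39 in H23, so the numbers were taken to pair the libraries. The main fits, chosen before, do not use this pairing, so their counts ignore it. The replicate block within each line uses it, and many counts differ under that block. GC content and length were available for 97.7% of the genes.

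The fits were tested on simulated data with 200 changed genes per comparison. Of genes changed by a log2 value of 1, the GSK-J4 fits recovered 92.5% in HCC827, 93% in H23 and 92.5% in A549 among 11391 genes, and 100% for the mean over the lines. The siKDM6B fits recovered 0 of 200 in A549 and 0 of 200 in H23 at that size, and 118 of 200 for the mean over both lines, among 10754 genes. At a log2 change of 2 they recovered 79.5%, 82.5% and 93.5%. In simulated data with 1 lowered list, camera called that list and 0 of 30 unchanged lists. The simulated noise was independent between genes, with the same spread for a gene in every library and no pairing of replicates. These checks therefore cannot speak for lists whose genes vary together, or for lines that differ in spread.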

Results

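The data are the RPKM of 11568 genes in 20 libraries of the lung adenocarcinoma lines HCC827, H23 and A549. GSK-J4, an inhibitor of the histone H3 lysine 27 demethylases KDM6A (UTX) and KDM6B (JMJD3), or DMSO was given to all 3 lines, with 2 libraries per group. A549 and H23 also have 2 siNT and 2 siKDM6B libraries each. The depth of the libraries is unknown. The lines stood apart as separate cell lines in genes chosen as line markers. EGFR, a receptor tyrosine kinase, averaged 438 ± 58.6 RPKM in HCC827 DMSO, 15.4 in H23 DMSO and 28.8 in A549 DMSO. AKR1B10, an aldo-keto reductase, averaged 1330 RPKM in A549 DMSO, 1.40 in HCC827 and 0.115 in H23. CDKN2A, a cell cycle inhibitor, averaged 0.615 RPKM in A549, 23.9 in H23 and 200 in HCC827. Markers of other cell types were mostly unlisted: the table held 3 of 10 fibroblast genes, 2 of 12 leukocyte genes and 1 of 9 endothelial genes, too few to test as lists. The fibroblast collagen COL1A1 reached at most 3.06 RPKM in any group and the endothelial cadherin CDH5 0.215. The macrophage marker CD68 averaged 47.1 RPKM in HCC827 DMSO, 12.9 in A549 DMSO and 3.52 in H23 DMSO, and the fibroblast proteoglycan LUM 6.44, 0.11 and 0.56.

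KDM6B, the target of the siRNA, was read in every library to check the labels. Under GSK-J4 its mRNA rose in H23 from 6.23 ± 0.79 to 14.5 ± 0.13 RPKM, a log2 change of 1.10 (SE 0.11, limma adjusted p = 2.1e-05), and in A549 from 2.29 ± 0.43 to 4.53 ± 0.58, a change of 0.75 (adjusted p = 0.00059). In HCC827 it stood at 6.07 ± 0.18 and 5.46 ± 0.064 RPKM and did not pass the test (log2 change -0.13, adjusted p = 1). KDM6A rose by 0.59 in H23 (adjusted p = 0.00042) and did not pass in A549 (0.14, adjusted p = 0.29). In the siRNA experiment, H23 siNT libraries had 4.12 and 3.92 RPKM of KDM6B and H23 siKDM6B libraries 1.95 and 2.39. A549 siNT libraries had 1.91 and 2.33, and the siKDM6B libraries 2.14 and 0.878. The library labelled A549 siKDM6B replicate 1 thus lay between the control libraries, and its label is in doubt wherever a direction is drawn from it. The change of KDM6B over both lines was -0.51 (SE 0.18) and did not pass (adjusted p = 0.28). Without the library labelled A549 siKDM6B replicate 1 it was -0.70 and passed (adjusted p = 0.0231), and without A549 siKDM6B replicate 2 it was -0.33. In the fit of all 20 libraries it was -0.51 with an adjusted p of 0.0237. That joint fit shares a spread per gene over groups that differ in spread. The median replicate SD (log2) was 0.210 in A549 siNT and 0.317 in A549 siKDM6B, against 0.061 to 0.086 in the GSK-J4 groups. The p-values of the joint fit may thus be too small where A549 siRNA libraries enter and too large elsewhere. KDM6B lies on chromosome 17 at 7839904 to 7854796 in GENCODE 29 on GRCh38, which is another build than that of the deposited values.

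**Figure D1:**
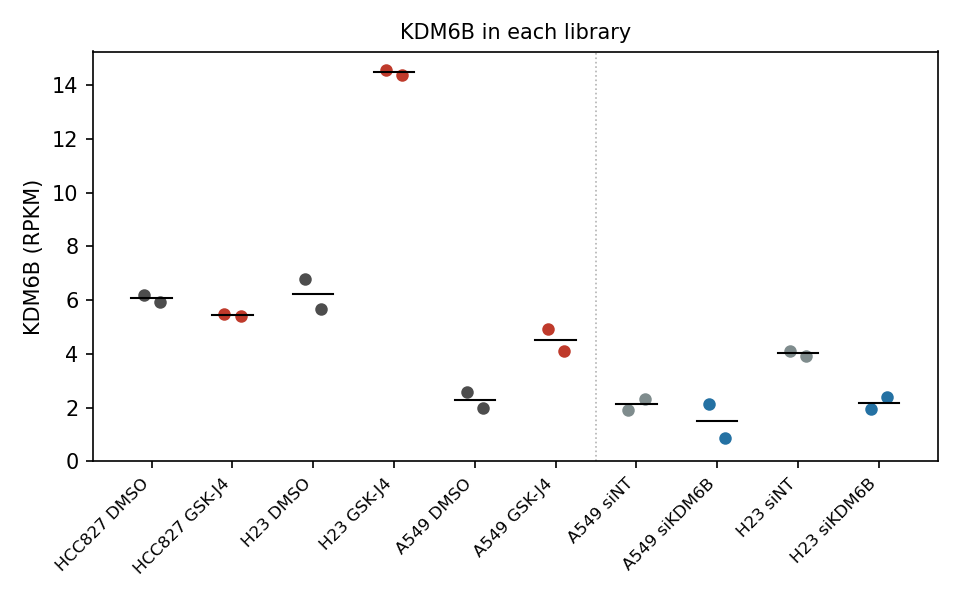
KDM6B in RPKM (vertical axis) in each of the 20 libraries (points) by group, with the group mean as a line and the siRNA experiment right of the dotted line. H23 GSK-J4 libraries averaged 14.5 RPKM against 6.23 under DMSO, and the library labelled A549 siKDM6B replicate 1 stood at 2.14 between the siNT libraries at 1.91 and 2.33.

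What GSK-J4 did in H23 was asked by comparing its 2 treated with its 2 DMSO libraries. SESN2, a stress-induced regulator of amino acid sensing, rose 15.1-fold from 4.11 ± 0.11 to 77.0 ± 15 RPKM (n = 2, log2 SE 0.16, limma adjusted p = 1.3e-07). TRIB3, a pseudokinase induced by ATF4, rose 10.6-fold, the stress transcription factor DDIT3 (CHOP) 10.5-fold, the metallothionein MT1F 9.89-fold and the secreted glycoprotein STC2 7.74-fold. CDH1, the epithelial cadherin, fell from 9.12 ± 0.60 to 1.05 ± 0.23 RPKM (log2 change -2.31, SE 0.14, adjusted p = 5.5e-07). CYP1B1, a cytochrome P450 monooxygenase, fell by 2.65 on the log2 scale, the chemokine CCL2 by a log2 change of -1.83, the mitochondrial carrier UCP2 by a change of -1.75 and the immunoproteasome subunit PSMB9 by a change of -1.62. In all, limma called 5229 of 11391 genes, 3368 higher and 1861 lower, of which 271 rose and 88 fell at least 2-fold. The direction of small changes depends on the scaling: with quantile normalization 2443 were higher and 2595 lower, and with median ratios 2679 and 2441. With all 20 libraries in a joint fit 2126 genes were called.

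Of 32 measured genes of the ATF4 integrated stress response, 31 rose in H23 (31 adjusted over the list alone), with a median log2 change of 1.38; examples beside SESN2 and TRIB3 are the serine synthesis enzyme PSAT1 (1.62) and CBS of the transsulfuration pathway (1.35). The list passed camera with an adjusted p of 3.6e-18, and had an adjusted p = 0.13 with an estimated correlation. Mitosis and G2/M genes fell in 40 of 41 members (40 adjusted over the list alone), among them cyclin B1 (CCNB1, -1.37) and the spindle midzone protein PRC1 (-1.19). Their median was -0.98 (camera adjusted p = 7.9e-28, adjusted p = 0.16 with an estimated correlation). DNA replication and G1/S genes fell in 41 of 42 (42 adjusted over the list alone), with cyclin E1 (CCNE1) at -1.28 and thymidylate synthase (TYMS) at -1.22. This list's median was -0.70 (camera adjusted p = 6.2e-23, adjusted p = 0.25 with an estimated correlation). Hypoxia-inducible genes rose in 24 of 28 and fell in 1 (26 and 1 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 2.1e-11, adjusted p = 0.13 with an estimated correlation); the glucose transporter SLC2A3 rose by 2.10 and hexokinase HK2 by 1.98. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and so also report on RNA selection, rose in 10 of 11 (10 adjusted over the list alone), HIST1H2AC by 2.28 and HIST1H4H by 2.30. Their median change was 1.47 (camera adjusted p = 1.8e-05, adjusted p = 0.092 with an estimated correlation). Metallothionein and zinc transport genes rose in 5 of 7 (5 adjusted over the list alone), with MT1X at 1.83 and the zinc exporter SLC30A1 at 1.46. Camera gave the list an adjusted p of 0.0071 at a median of 1.35 (adjusted p = 0.16 with an estimated correlation). Of 23 p53 target genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone), the cell cycle inhibitor CDKN1A by 1.41. Their median was 0.30 (camera adjusted p = 0.033, adjusted p = 0.29 with an estimated correlation). HOX and other developmental genes bound by the Polycomb complex PRC2 rose in 13 of 26 and fell in 3 (13 and 3 adjusted over the list alone). As a list they did not pass camera (adjusted p = 0.35) but passed fry (adjusted p = 0.0032). The ATF4, mitosis, replication, hypoxia, histone, metallothionein and p53 lists in H23 also passed fry (adjusted p from 9.3e-06 to 0.00065).

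In A549 the same comparison was made. BEX2, a small adaptor protein, rose 15.9-fold from 1.36 ± 0.057 to 39.0 ± 20 RPKM (n = 2, log2 SE 0.28, limma adjusted p = 4.4e-06), and MT1F rose 13.3-fold from 3.44 ± 0.43 to 58.5 ± 10 (adjusted p = 3.1e-08). The stress-induced FAM129A (niban) rose 10.2-fold, the protease inhibitor CSTA 8.61-fold and DDIT3 6.5-fold. Fibrinogen chains fell: FGB from 14.3 ± 0.17 to 2.44 ± 0.81 RPKM (log2 change -2.18, SE 0.12, adjusted p = 1.6e-06) and FGA from 20.2 to 5.53 (-1.75, adjusted p = 5.3e-05). The proliferation marker MKI67 fell by 1.53, the meiotic recombinase gene DMC1 by a change of -1.55 and the uncharacterised C11orf86 by a change of -1.55. In all 3615 genes were called, 2455 higher and 1160 lower (1634 and 1757 with quantile normalization, 1929 and 1527 with median ratios), of which 118 rose and 53 fell at least 2-fold. The count was 753 with all 20 libraries in a joint fit, 2376 with the 4 libraries of the comparison alone, 2352 without A549 DMSO replicate 1, 1888 without A549 DMSO replicate 2 and 1953 without A549 GSK-J4 replicate 2.

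The ATF4 list rose in A549 in 30 of 32 members (30 adjusted over the list alone), with SESN2 at 2.52, the stress regulator NUPR1 at 2.55 and CBS at 2.09. This list's median was 1.16 (camera adjusted p = 1.2e-21, adjusted p = 0.13 with an estimated correlation). Mitosis and G2/M genes fell in 40 of 41 (40 adjusted over the list alone), including CCNB1 (-1.01) and NUSAP1 (-1.09), both needed for mitosis. Their median change was -0.98 (camera adjusted p = 6.9e-40, adjusted p = 0.14 with an estimated correlation). DNA replication and G1/S genes fell in 38 of 42 (39 adjusted over the list alone), with thymidine kinase TK1 at -1.05. Camera gave the list an adjusted p of 2.2e-25 at a median of -0.55 (adjusted p = 0.21 with an estimated correlation). Of 23 p53 target genes, 19 rose (20 adjusted over the list alone), CDKN1A by 1.81 and GADD45A, a DNA damage response gene, by 1.77. Their median was 0.63 (camera adjusted p = 1.0e-09, adjusted p = 0.049 with an estimated correlation). Genes of cholesterol synthesis and uptake fell in 19 of 25 and rose in 1 (20 and 1 adjusted over the list alone), among them the reductase DHCR7 (-1.19). This list's median was -0.44 (camera adjusted p = 8.9e-12, adjusted p = 0.14 with an estimated correlation). Hypoxia-inducible genes fell in 8 of 28 and rose in 4 (8 and 4 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0035, adjusted p = 0.36 with an estimated correlation, and 0.16 by camera without A549 GSK-J4 replicate 1, where the median was -0.058; it was -0.089 without A549 DMSO replicate 2 and -0.22 without A549 GSK-J4 replicate 2); SLC2A3 fell by 1.07 and the prolyl hydroxylase EGLN3 by a change of -1.03. Metallothionein and zinc transport genes rose in 4 of 7 (4 adjusted over the list alone), with MT1X at 2.14 and MT2A at 1.86. Their median change was 0.74 (camera adjusted p = 0.0071, adjusted p = 0.19 with an estimated correlation). By fry this list and the ATF4, mitosis, replication, p53 and cholesterol lists passed in A549 (adjusted p from 2.4e-05 to 0.0027). The hypoxia list did not pass fry there (adjusted p = 0.054). HOX and PRC2-bound genes rose in 9 of 26 and fell in 1 (10 and 1 adjusted over the list alone). HOXB9 rose by 0.89 and HOXD8 by 0.80, and the median of the list was 0.24 (fry adjusted p = 0.0016). That list passed camera at an adjusted p of 0.043 (adjusted p = 0.36 with an estimated correlation) and did not pass with quantile normalization (median 0.09, 0.18), with a pseudocount of 0.1 (0.070), without A549 DMSO replicate 1 (0.075), without A549 GSK-J4 replicate 1 (0.078), or with the within-line replicate block and GC and length removal (0.12).

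In HCC827 few genes responded. MT1F rose 2.37-fold from 7.38 ± 0.63 to 18.9 ± 2.0 RPKM (n = 2, log2 SE 0.14, limma adjusted p = 0.014), and PHGDH, the entry enzyme of serine synthesis, rose 2.44-fold from 7.25 ± 0.057 to 19.4 ± 4.4 (adjusted p = 0.015). TGIF2-C20orf24, a readthrough transcript whose reads overlap those of its parent genes, rose 3.10-fold from 5.50 ± 1.6 to 18.9 ± 2.6 (adjusted p = 0.034), and did not pass with quantile normalization (0.077), with median ratios (0.060), with a pseudocount of 0.1 (0.054), with no filter (0.052) or without any of the 4 libraries in turn (0.0941 to 0.425). These were the 3 genes limma called among 11391, all higher, with 346 at an unadjusted p under 0.05. Without HCC827 DMSO replicate 1 or HCC827 DMSO replicate 2 limma called 0 genes, with 220 and 447 at an unadjusted p under 0.05, and MT1F and PHGDH did not pass without HCC827 DMSO replicate 1 (0.122 and 0.241), DMSO replicate 2 (0.125 and 0.133) or GSK-J4 replicate 2 (both 0.113). With a replicate block 6 genes passed, adding MT1X (1.14, adjusted p = 0.0028) and MT2A (0.97, adjusted p = 0.0042), and 11 passed with the block within each line.

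As a list, interferon-stimulated genes rose in HCC827: 27 of 27 members had a positive change, with a median of 0.25 (camera adjusted p = 9.7e-24, adjusted p = 0.017 with an estimated correlation, fry adjusted p = 0.017). None of them passed over all genes (limma, 0 called, 13 at an unadjusted p under 0.05), and 5 passed adjusted over the list alone; the antiviral genes OAS2, XAF1 and MX1 had log2 changes of 0.69, 0.60 and 0.59, and OAS2 and XAF1 passed without HCC827 GSK-J4 replicate 2 (adjusted p = 0.0109 and 0.0321). The ATF4 list was higher by a median of 0.17, with 1 of 32 members called (PHGDH) and 4 adjusted over the list alone (camera adjusted p = 1.1e-14, adjusted p = 0.20 with an estimated correlation). The ATF4 median was 0.26 without HCC827 GSK-J4 replicate 1 and 0.075 without replicate 2. Metallothionein and zinc transport genes had 1 of 7 called and 3 adjusted over the list alone (median 0.08, mean 0.47, camera adjusted p = 5.3e-05, adjusted p = 0.11 with an estimated correlation). Their median was 0.24 without HCC827 DMSO replicate 1, 0.00081 without DMSO replicate 2 and 0.17 without GSK-J4 replicate 2. Mitosis and G2/M genes were negative in 36 of 41, by a median of only -0.10 (camera adjusted p = 4.3e-07, adjusted p = 0.70 with an estimated correlation), with 0 called by limma and 3 at an unadjusted p under 0.05. By fry the ATF4, metallothionein and mitosis lists in HCC827 did not pass (adjusted p = 0.29, 0.16 and 0.92).

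Averaged over the 3 lines, GSK-J4 raised stress and metal response genes. MT1F rose 6.78-fold (log2 SE 0.08, limma adjusted p = 3.5e-09), SESN2 4.49-fold, DDIT3 4.43-fold and TRIB3 4.21-fold. CHAC1, which degrades glutathione, rose 3.64-fold, PHGDH 3.26-fold, MT1X 3.26-fold, STC2 3.25-fold, PPP1R15A (GADD34) 2.87-fold and the stress cytokine GDF15 2.73-fold. Among called genes that moved the same way in each line, those with the largest falls act in mitosis and the cell cycle. KIF20A, a mitotic kinesin, fell by 1.03 on the log2 scale (SE 0.09, limma adjusted p = 1.0e-05) and MKI67 by a change of -0.99. CDCA3, the kinase PLK1, the inhibitor CDKN2C, CENPF, the kinase AURKA, TROAP, ANLN and SPAG5 had changes from -0.97 to -0.85. In all 5002 of 11391 genes were called, 3364 higher and 1638 lower (2374 and 2491 with quantile normalization, 2672 and 2236 with median ratios), of which 40 rose and 1 fell at least 2-fold. The count was 1761 with all 20 libraries in a joint fit and 2456 in the additive fit.

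In the mean of the 3 lines, all 32 ATF4 genes rose (32 adjusted over the list alone, median 0.90, camera adjusted p = 7.5e-22). All 41 mitosis genes fell in that mean (41 adjusted over the list alone, median -0.69, camera adjusted p = 2.1e-36). HCC827 alone had 1 ATF4 gene and 0 mitosis genes called. The metallothionein list rose in 5 of 7 (5 adjusted over the list alone; median 0.74, camera adjusted p = 0.0017), with MT2A at 1.2. For these 3 lists the adjusted p was 0.12 by camera with an estimated correlation, and from 1.0e-05 to 6.5e-05 by fry. DNA replication genes fell in 42 of 42 (42 adjusted over the list alone), with MCM4, a subunit of the replicative helicase, at -0.61. Camera gave the list an adjusted p of 2.5e-26 at a median of -0.42 (adjusted p = 0.20 with an estimated correlation). ERK feedback and immediate-early genes rose in 20 of 23 and fell in 1 (21 and 1 adjusted over the list alone). Their median was 0.24 (camera adjusted p = 2.0e-05, adjusted p = 0.12 with an estimated correlation). The phosphatase genes DUSP5 and DUSP6 rose by 1.24 and 0.68 and EGR1 by 0.73. Genes of the KDM6 and PRC2 complexes went both ways, with 6 of 19 higher and 7 lower (6 and 7 adjusted over the list alone), and did not pass as a list (camera adjusted p = 0.14). KDM6B rose in the mean by 0.57 (limma adjusted p = 4.6e-05) and KDM6A by 0.25 (limma adjusted p = 0.0038, and 0.0697 in the additive fit). HCC827 did not share the rise of KDM6B, which read 6.19 and 5.94 RPKM under DMSO and 5.5 and 5.41 under GSK-J4.

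**Figure D2:**
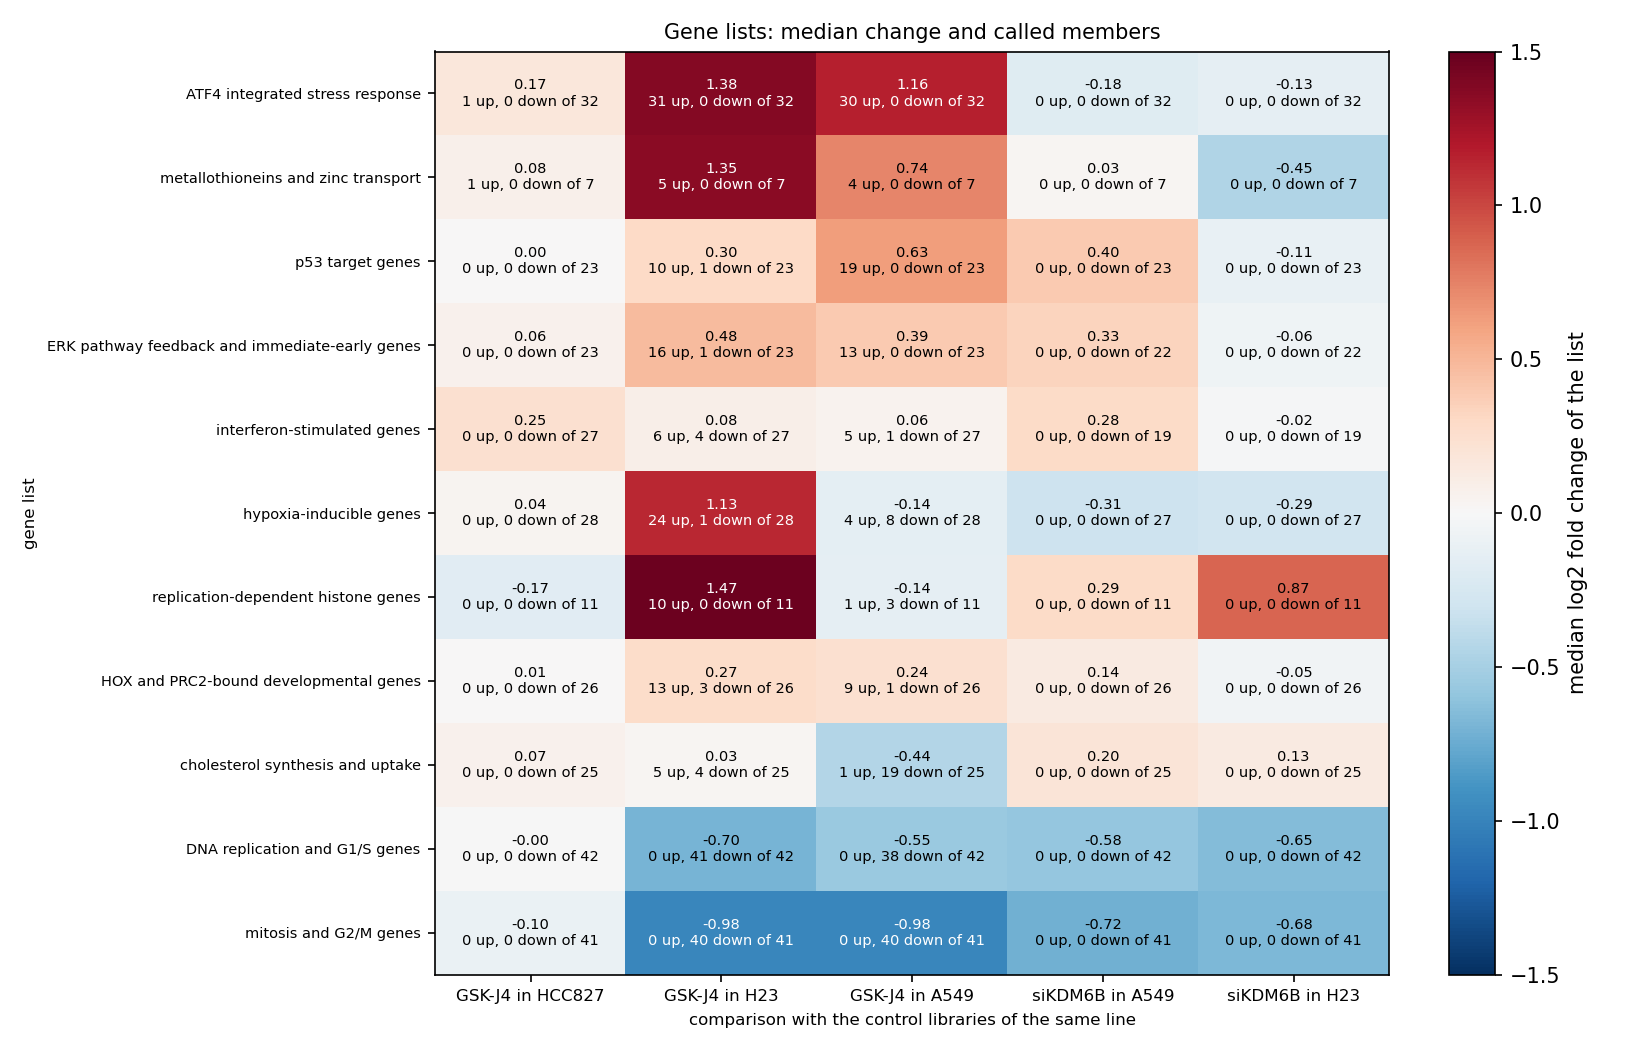
Median log2 fold change (colour and upper number) of 11 gene lists (vertical axis) in 5 comparisons with the control libraries of the same line (horizontal axis), with the called members of each list. The ATF4 list had medians of 1.38 in H23 and 1.16 in A549 under GSK-J4, and the mitosis list -0.98 in both; under siKDM6B limma called 0 members of each list.

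Whether H23 responded otherwise than HCC827 was tested as a difference of effects. SESN2 rose more in H23 than in HCC827 by 3.86 (SE 0.23, limma adjusted p = 5.1e-06); in HCC827 it stood at 3.24 ± 0.30 and 3.42 ± 0.33 RPKM. TRIB3 differed by 3.23, DDIT3 by 3.04, STC2 by 2.77 and TSC22D3 (GILZ) by 2.65. CDH1 differed by -2.22 (adjusted p = 4.4e-05), CYP1B1 by -2.92, PSMB9 by -1.85, UCP2 by -1.82 and TGIF2-C20orf24 by -1.81, and KDM6B by 1.23 (adjusted p = 0.00035). The ATF4 list differed in 30 of 32 genes (30 adjusted over the list alone). This list's median was 1.21 (camera adjusted p = 2.5e-17, adjusted p = 0.14 with an estimated correlation). Hypoxia-inducible genes differed in 24 of 28 (24 adjusted over the list alone), SLC2A3, near the floor in HCC827, by 2.07. Their median change was 0.97 (camera adjusted p = 1.4e-11, adjusted p = 0.12 with an estimated correlation). Mitosis genes were lower in H23's effect in 35 of 41 (39 adjusted over the list alone), with CCNB1 at -1.30. Camera gave the list an adjusted p of 2.1e-26 at a median of -0.88 (adjusted p = 0.22 with an estimated correlation). Replication-dependent histone genes rose more in H23 in 9 of 11 (10 adjusted over the list alone), HIST1H4H by 2.62 and HIST1H2AC by 2.46. For the histone list the median was 1.56 (camera adjusted p = 2.4e-06, adjusted p = 0.059 with an estimated correlation). In all 3183 genes differed, 2074 higher and 1109 lower (1427 and 1607 with quantile normalization, 1592 and 1562 with median ratios). The count was 576 with all 20 libraries in a joint fit (464 higher and 112 lower), 4788 with the replicate block within each line and 2112 without HCC827 DMSO replicate 1.

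A549 and HCC827 were compared in the same way. BEX2 rose more in A549 by 4.07 (SE 0.39, limma adjusted p = 0.00025), FAM129A by 3.35, CSTA by 3.11 and MT1F by 2.49. DMC1 differed by -2.25, FGB by -2.16, TGIF2-C20orf24 by -1.98 and C11orf86 by -1.84; in the 4 HCC827 libraries FGB was near the floor, FAM129A read 0.15 to 0.17 RPKM and CSTA read 0.1. RPS10-NUDT3 was also called and is uncertain (adjusted p = 0.045). RPS10-NUDT3, a readthrough transcript, read 0.1 in both HCC827 DMSO libraries, 4.42 and 1.3 in HCC827 GSK-J4, 4.17 and 1.72 in A549 DMSO and 3.03 and 0.91 in A549 GSK-J4. RPS10-NUDT3 did not pass without HCC827 DMSO replicate 1 (0.113) or 2 (0.0968), HCC827 GSK-J4 replicate 1 (0.137), A549 DMSO replicate 1 (0.135) or A549 GSK-J4 replicate 2 (0.154). KDM6B differed by 0.88 (adjusted p = 0.0059). The ATF4 list differed in 26 of 32 genes (26 adjusted over the list alone), CBS by 1.99. Their median was 0.99 (camera adjusted p = 7.2e-20, adjusted p = 0.12 with an estimated correlation). Mitosis genes were lower in 39 of 41 (40 adjusted over the list alone). This list's median was -0.90 (camera adjusted p = 1.8e-39, adjusted p = 0.12 with an estimated correlation). Of 23 p53 target genes, 14 rose more in A549 (15 adjusted over the list alone), the apoptosis gene BBC3 by 1.64 and CDKN1A by 1.39. Their median change was 0.68 (camera adjusted p = 9.2e-10, adjusted p = 0.048 with an estimated correlation). In all 1464 genes differed, 978 higher and 486 lower (668 and 731 with quantile normalization, 716 and 708 with median ratios), or 2523 with a replicate block and 2992 with the block within each line. With all 20 libraries in a joint fit 67 differed, 63 higher and 4 lower. The count fell to 616 without HCC827 DMSO replicate 1, 903 without HCC827 DMSO replicate 2, 975 without HCC827 GSK-J4 replicate 1, 909 without A549 DMSO replicate 1, 658 without A549 DMSO replicate 2 and 749 without A549 GSK-J4 replicate 2.

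H23 and A549 shared much of their response and differed in part. Of 11391 genes, 1520 were called higher in both lines, against 725.9 for independent lists, 730 were called lower in both, against 189.5, and 114 were called in opposite directions. The log2 changes correlated at a Pearson r of 0.60 and a Spearman rho of 0.57 across genes, which are not independent replicates. SLC2A3 rose in H23 from 36.8 ± 7.4 to 159 ± 0.092 RPKM and fell in A549 from 14.2 ± 0.87 to 6.22 ± 0.15, a difference of 3.17 (SE 0.16, limma adjusted p = 1.5e-06). The hypoxia-induced ANKRD37 differed by 3.02, the binding protein IGFBP3 by 2.98, the myosin MYO10 by 2.52 and the reductase DHRS2 by 2.45. CYP1B1 differed by -3.30, the calcium-binding S100P by -2.73, NUPR1 by -2.40, CDH1 by -2.20 and the urokinase gene PLAU by -2.08. In the 4 H23 libraries S100P read at most 0.36 RPKM and NUPR1 at most 0.3, so their differences rest on the rise in A549. Hypoxia-inducible genes rose more in H23 in 25 of 28 (27 adjusted over the list alone). Camera gave the list an adjusted p of 6.4e-26 at a median of 1.23 (adjusted p = 0.015 with an estimated correlation). Histone genes did so in 10 of 11 (10 adjusted over the list alone). Their median was 1.53 (camera adjusted p = 1.1e-10, adjusted p = 0.012 with an estimated correlation). Cholesterol genes did so in 14 of 25 (18 adjusted over the list alone; median 0.53, camera adjusted p = 2.1e-07), the sterol transporter STARD4 by 1.70, and glycolysis enzymes in 11 of 19 (13 and 1 lower adjusted over the list alone; median 0.51, camera adjusted p = 1.7e-08), the aldolase ALDOC by 1.75. For these last lists the adjusted p was 0.28 with an estimated correlation. KDM6B did not differ past the threshold (0.35, adjusted p = 0.18, and 0.0397 with the block within each line). KDM6A did not either (0.45, adjusted p = 0.051), but passed with a replicate block (0.021) and with a pseudocount of 0.1 (0.0496). In all 1341 genes differed, 691 higher and 650 lower, or 2331 with a replicate block and 2821 with the block within each line; the count was 154 with all 20 libraries in a joint fit, 635 without H23 DMSO replicate 1, 668 without H23 GSK-J4 replicate 2, 751 without A549 DMSO replicate 1 and 740 without A549 DMSO replicate 2.

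Knockdown of KDM6B asks whether loss of a target enzyme of GSK-J4 gives the same changes. In A549 limma called 4 of 10754 genes (898 at an unadjusted p under 0.05), all with an arm at the floor, so only library values are given. HMGB1, a chromatin protein, read 51.0 and 48.2 RPKM in siNT, and 0.1 in A549 siKDM6B replicate 2 and in the library labelled A549 siKDM6B replicate 1. PTCD1, a mitochondrial RNA-binding protein, read 2.0 and 2.83 in siNT and the transcription factor TGIF2 3.29 and 4.70; both read 0.1 in A549 siKDM6B replicate 2 and in the library labelled A549 siKDM6B replicate 1. FAM118B read 0.1 in both siNT libraries, 5.67 in the library labelled A549 siKDM6B replicate 1 and 8.34 in replicate 2. DNA replication genes were lower as a list (median -0.58, camera adjusted p = 5.0e-19). The adjusted p was 0.69 by camera with an estimated correlation and 0.40 by fry. Limma called 0 of 42, with 22 at an unadjusted p under 0.05 and 10 adjusted over the list alone. POLA1, a DNA polymerase subunit, had a change of -1.12. Mitosis genes were lower by a median of -0.72 (camera adjusted p = 7.9e-18, adjusted p = 0.69 with an estimated correlation), with 0 of 41 called by limma, 18 at an unadjusted p under 0.05 and 0 adjusted over the list alone; cyclin A2 (CCNA2) had a change of -1.39. With the library labelled A549 siKDM6B replicate 1 as the sole treated library, the mitosis median was -0.45. The p53 targets were higher by a median of 0.40 (camera adjusted p = 2.8e-05, adjusted p = 0.69 with an estimated correlation), with 0 of 23 called by limma, over all genes or adjusted over the list alone, and 4 at an unadjusted p under 0.05. The p53 median was 0.22 without A549 siNT replicate 1, 0.66 without A549 siNT replicate 2 and 0.24 without A549 siKDM6B replicate 2. These lists moved alongside a trend of the change with GC content (Spearman rho 0.44 across genes) and transcript length (-0.30). The count was 579 with all 20 libraries in a joint fit, 1 with the 4 libraries of the comparison alone, 147 without the library labelled A549 siKDM6B replicate 1, 28 without A549 siKDM6B replicate 2 and 11 without A549 siNT replicate 1. It was 2 with a replicate block, where PTCD1 and TGIF2 had an adjusted p of 0.069, and 0 without genes at the floor (890 of 10691 at an unadjusted p under 0.05). Without A549 siNT replicate 2, FAM118B (0.0511), TGIF2 (0.115) and PTCD1 (0.129) did not pass.

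In H23, where KDM6B was lower in both siKDM6B libraries, limma called 5 of 10754 genes (879 at an unadjusted p under 0.05), again all at the floor in an arm. The spread in this fit is pooled with A549, where it was larger. The median replicate SD (log2) was 0.210 in A549 siNT and 0.317 in A549 siKDM6B, against 0.0883 and 0.107 in H23. EMC1, a membrane insertion factor, read 0.1 in both siNT libraries and 15.7 and 16.1 RPKM under siKDM6B, and FAM118B read 0.1 in both siNT libraries and 7.73 and 7.23 under siKDM6B. ANAPC11, a subunit of the anaphase-promoting complex, read 10.6 and 12 in siNT, the galectin LGALS8 6.08 and 4.29, and PTCD1 2.79 and 3.16, each with 0.1 in both siKDM6B libraries. DNA replication genes were lower by a median of -0.65 (camera adjusted p = 2.1e-21, adjusted p = 0.99 with an estimated correlation), with 0 of 42 called by limma, 28 at an unadjusted p under 0.05 and 24 adjusted over the list alone; MCM6 of the replicative helicase had a change of -1.37. Mitosis genes were lower by a median of -0.68 (camera adjusted p = 6.5e-16, adjusted p = 0.99 with an estimated correlation), with 0 of 41 called by limma, 14 at an unadjusted p under 0.05 and 1 adjusted over the list alone. Without H23 siKDM6B replicate 1 the median was -0.35 for mitosis and -0.42 for replication genes, and without H23 siKDM6B replicate 2 it was -1.06 for mitosis genes. Histone genes were higher by a median of 0.87 (camera adjusted p = 0.0020, adjusted p = 0.99 with an estimated correlation, and 0.17 by camera without H23 siKDM6B replicate 1), with 0 of 11 called by limma, 3 higher and 1 lower at an unadjusted p under 0.05 and 3 higher adjusted over the list alone. The count was 1 without H23 siNT replicate 2 or H23 siKDM6B replicate 1, 8 with a pseudocount of 0.1, 3 with no filter (ANAPC11 and LGALS8 at 0.071), and 0 without genes at the floor (860 at an unadjusted p under 0.05). ANAPC11, LGALS8 and PTCD1 did not pass without any of the 4 libraries in turn (adjusted p from 0.0834 to 0.594), FAM118B without H23 siNT replicate 2 (0.116) or H23 siKDM6B replicate 1 (0.0889), and LGALS8 with a replicate block (0.094). Fitted on its 4 libraries alone, the comparison called 646 genes, 236 higher and 410 lower, with KDM6B at -0.67 (adjusted p = 0.035), and with all 20 libraries in a joint fit 632.

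Over both lines limma called 6 genes, 2 higher and 4 lower (1472 at an unadjusted p under 0.05). NUP43, a nuclear pore subunit, was the called gene without a floor arm: it read 11.9 and 11.2 RPKM in A549 siNT, 4.07 in the library labelled A549 siKDM6B replicate 1, 3.67 in A549 siKDM6B replicate 2, 25.9 and 22.7 in H23 siNT and 9.55 and 9.90 in H23 siKDM6B, a 2.47-fold fall (log2 change -1.30, SE 0.12, adjusted p = 0.019). Its call ended without the genes at the floor (adjusted p = 0.11) and without A549 siNT replicate 1 (0.062), A549 siNT replicate 2 (0.094), H23 siNT replicate 1 (0.18), H23 siNT replicate 2 (0.15), H23 siKDM6B replicate 1 (0.23) or H23 siKDM6B replicate 2 (0.15). The other calls were FAM118B and EMC1, higher, and HMGB1, PTCD1 and TGIF2, lower. TGIF2 did not pass without H23 siNT replicate 1 (0.0907) or 2 (0.0787), H23 siKDM6B replicate 1 (0.0962) or 2 (0.108), or in the additive fit (0.0567), where HMGB1 did not pass either (0.204). Replication genes were lower by a median of -0.62 in 42 of 42 members (camera adjusted p = 5.4e-24) and mitosis genes by -0.74 in 41 of 41 (camera adjusted p = 1.2e-20); with an estimated correlation the adjusted p was 0.81 for both. Over all genes limma called 0 members of either list, with 34 and 30 at an unadjusted p under 0.05; adjusted over the list alone 34 and 27 passed. With the block within each line limma called 13 replication and 19 mitosis genes over all genes, each lower. Among them the proliferation factor FOXM1 had a change of -1.13 (adjusted p = 0.12; 0.037 with quantile normalization and 0.041 with median ratios) and CCNA2 of -1.40 (adjusted p = 0.13). Both passed with the block within each line (0.0338) and without the library labelled A549 siKDM6B replicate 1 (0.0203 and 0.0167). The ATF4 list, raised by GSK-J4, had a median of -0.16 and did not pass (camera adjusted p = 0.085), with 0 of 32 called by limma, over all genes or adjusted over the list alone, and 4 lower at an unadjusted p under 0.05. That list passed in the lower direction without A549 siKDM6B replicate 2 (0.014), H23 siNT replicate 1 (0.031) or H23 siKDM6B replicate 2 (0.018).

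The count over both lines rests on few libraries. Without the library labelled A549 siKDM6B replicate 1, limma called 857 genes, 337 higher and 520 lower, including 19 mitosis and 20 replication genes, all lower. A549 siKDM6B replicate 2 was then the sole treated A549 library, so a gene at the floor in it had its whole A549 knockdown arm there. GTF2I, NCOA3 and RABEP1 read 0.1 RPKM in that library and far above the floor in the library labelled A549 siKDM6B replicate 1. Their fitted falls rest at least in part on that arm and bound no fold. How many called genes this holds for was not counted. Without A549 siNT replicate 1 the count was 14 and without A549 siKDM6B replicate 2 it was 25. With the replicate block within each line it was 395, 178 higher and 217 lower. Of these, 78 and 127 were shared with GSK-J4 over the lines against 52.7 and 32.3 for independent lists, and 39 went the opposite way. It was 1517 with all 20 libraries in a joint fit (553 higher and 964 lower), 3 in the additive fit, 14 with quantile normalization, 12 with median ratios, and 0 without genes at the floor (1454 at an unadjusted p under 0.05).

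**Figure D3:**
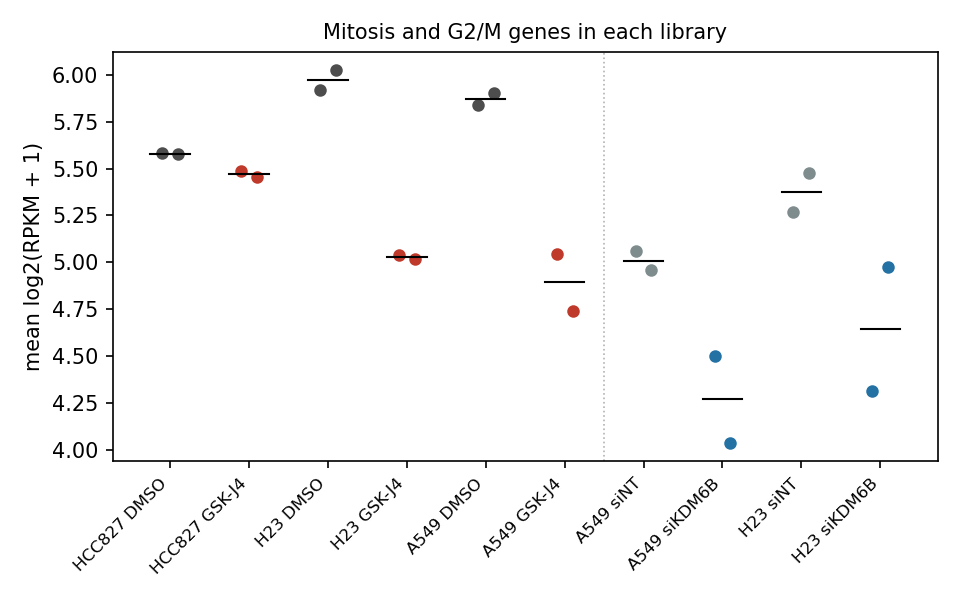
Mean log2(RPKM + 1) of the mitosis and G2/M genes (vertical axis) in each of the 20 libraries (points) by group, with the group mean as a line and the siRNA experiment right of the dotted line. H23 libraries fell from 5.92 and 6.02 under DMSO to 5.04 and 5.02 under GSK-J4, and the library labelled A549 siKDM6B replicate 1 stood at 4.50, below the siNT libraries at 5.06 and 4.96.

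**Figure D4:**
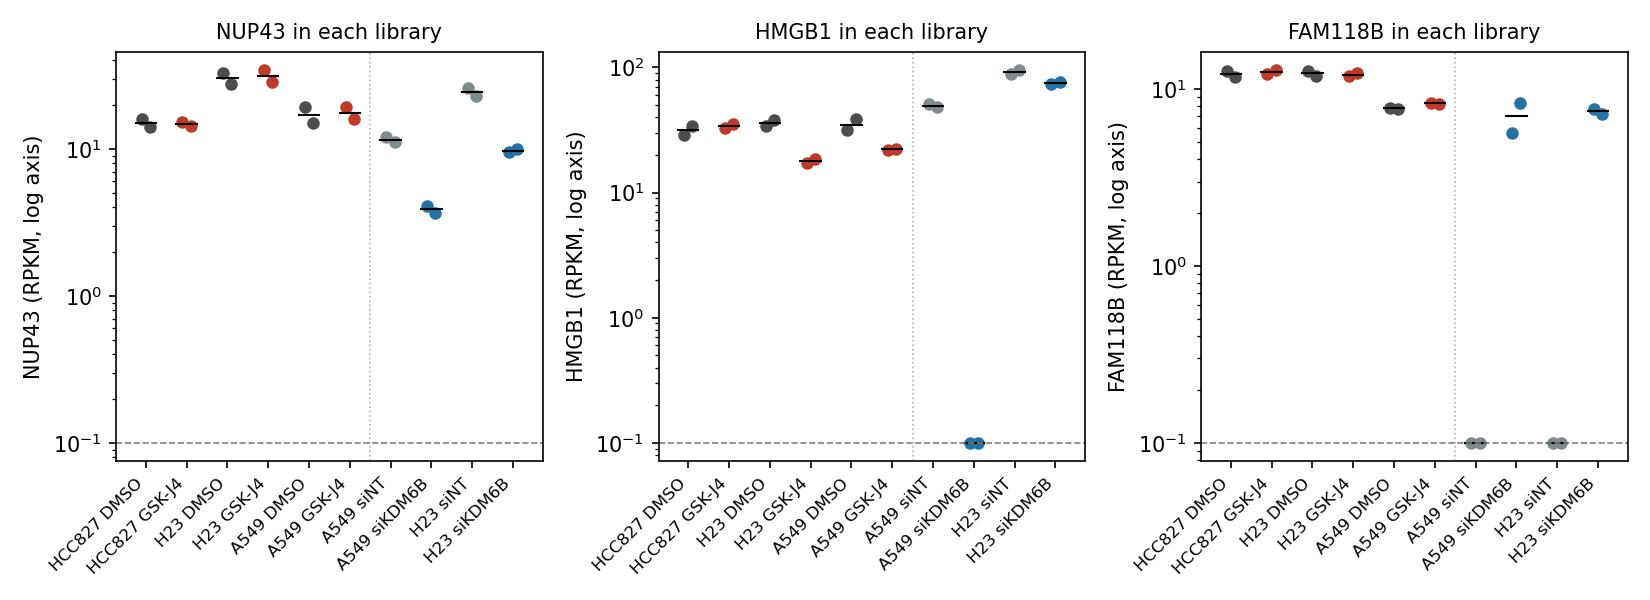
RPKM on a log axis of NUP43, HMGB1 and FAM118B in each of the 20 libraries (points) by group, with group means as lines, the floor of 0.1 as a dashed line and the siRNA experiment right of the dotted line. HMGB1 stood at 0.1 in both libraries labelled A549 siKDM6B and at 73.1 and 77.1 in H23 siKDM6B, while FAM118B stood at 0.1 in all 4 siNT libraries.

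The knockdown effects of the lines differed in 2 genes by limma (265 at an unadjusted p under 0.05), both at the floor in an arm. HMGB1 fell to 0.1 RPKM in A549 siKDM6B replicate 2 and the library labelled A549 siKDM6B replicate 1, and read 87.9 and 95.1 in H23 siNT and 73.1 and 77.1 in H23 siKDM6B. EMC1 was at 0.1 in both H23 siNT libraries and at 15.7 and 16.1 in H23 siKDM6B; it did not pass without H23 siNT replicate 1 (0.0556), H23 siKDM6B replicate 1 (0.0648) or H23 siKDM6B replicate 2 (0.0565). The p53 list differed by a median of -0.45 in H23 against A549 (camera adjusted p = 1.7e-07, adjusted p = 0.97 with an estimated correlation), with 0 of 23 members called by limma, over all genes or adjusted over the list alone, and 3 at an unadjusted p under 0.05. The p53 median was -0.71 without A549 siNT replicate 2 and -0.28 without A549 siKDM6B replicate 2. FDXR, a p53-induced reductase, differed by -1.22 and DDB2 of DNA repair by -0.99, both with an adjusted p of 1. The count was 9 without the library labelled A549 siKDM6B replicate 1, 10 without A549 siKDM6B replicate 2, 4 without A549 siNT replicate 1 or H23 siNT replicate 2, and 1 without H23 siKDM6B replicate 1 or H23 siKDM6B replicate 2. It was 19 with all 20 libraries in a joint fit, 4 with a pseudocount of 0.1 or with the replicate block within each line, and 0 without genes at the floor (253 at an unadjusted p under 0.05).

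Compound and knockdown were then compared in A549, each against its own controls, with the library labelled A549 siKDM6B replicate 1 in the knockdown arm. The spread was shared over all 20 libraries and was larger in the A549 siRNA groups, so the p-values of this comparison may be too small. FAM129A rose under GSK-J4 beyond its change under siKDM6B by 3.39 (SE 0.20, limma adjusted p = 5.6e-07), MT1F by 3.28, BEX2 by 3.15 and CSTA by 2.99. C11orf86 differed by -2.45 (adjusted p = 0.0011), the nucleoside transporter SLC29A4 by -1.66 and the cytokine IL32 by -1.58 (adjusted p = 0.032, 0.052 with median ratios). HMGB1, FAM118B and LCORL were called with an arm at the floor; LCORL read 0.1 in both siNT libraries, 1.71 in the library labelled A549 siKDM6B replicate 1 and 1.27 in replicate 2. MT1F did not pass without A549 DMSO replicate 1 (0.0681), A549 DMSO replicate 2 (0.0915) or A549 GSK-J4 replicate 2 (0.0950), nor IL32 without either DMSO library (0.0768 and 0.143), either GSK-J4 library (0.0854 and 0.112) or A549 siNT replicate 2 (0.0663). KDM6B differed by 1.11 (adjusted p = 0.059, 0.043 with a replicate block, 0.00044 without the library labelled A549 siKDM6B replicate 1 and 0.031 without A549 siKDM6B replicate 2) and NUP43 by 1.41 (adjusted p = 0.0041). The ATF4 list was higher under GSK-J4 in 14 of 32 genes (20 adjusted over the list alone), with asparagine synthetase ASNS at 2.48. This list's median was 1.5 (camera adjusted p = 2.8e-20, adjusted p = 0.12 with an estimated correlation). The mitosis list differed by a median of -0.26 (camera adjusted p = 0.00077, adjusted p = 0.86 with an estimated correlation), with 0 of 41 called by limma, over all genes or adjusted over the list alone, and 2 at an unadjusted p under 0.05. It did not pass with quantile normalization (-0.23, 0.068), without A549 GSK-J4 replicate 2 (0.051) or without A549 siNT replicate 2 (0.31), and its sign turned without the library labelled A549 siKDM6B replicate 1 (0.04, 0.80). In all 195 of 11419 genes differed, 155 higher and 40 lower (146 and 108 with quantile normalization, 111 and 92 with median ratios), or 1113 with the replicate block within each line. The count was 84 without A549 DMSO replicate 1, 67 without A549 DMSO replicate 2, 78 without A549 GSK-J4 replicate 2, 1523 without the library labelled A549 siKDM6B replicate 1 and 1101 without A549 siKDM6B replicate 2.

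In H23 the effect of GSK-J4 exceeded that of siKDM6B by 3.68 for MT1F (SE 0.64, limma adjusted p = 0.0040), by 3.67 for STC2 (adjusted p = 7.0e-06), by 3.55 for SESN2 and by 3.06 for TRIB3. CDH1 differed by -2.48 (adjusted p = 0.00041), KDM6B by 1.77 (adjusted p = 0.0015) and NUP43 by 1.29 (adjusted p = 0.0027), while KDM6A did not pass (0.53, adjusted p = 0.058, and 0.033 with a replicate block). ANAPC11, EMC1, FAM118B, METTL5 and DOLK were called with an arm at the floor; METTL5, an RNA methyltransferase, read 0.1 in both siNT libraries and 52.2 and 53.6 RPKM under siKDM6B, and the dolichol kinase DOLK 0.1 in both and then 4.07 and 5.70. The ATF4 list was higher under GSK-J4 in 19 of 32 genes (26 adjusted over the list alone), with PHGDH at 2.46. Their median change was 1.51 (camera adjusted p = 3.2e-16, adjusted p = 0.078 with an estimated correlation). Hypoxia-inducible genes were higher in 15 of 28 (20 adjusted over the list alone), with SLC2A1 at 2.70; the list's median was 1.24 (camera adjusted p = 1.2e-13, adjusted p = 0.036 with an estimated correlation). Metallothionein genes were higher in 5 of 7 (6 adjusted over the list alone), with MT1X at 3.01. For these the median was 1.49 (camera adjusted p = 3.5e-05, adjusted p = 0.078 with an estimated correlation). The mitosis list differed by a median of -0.14 (camera adjusted p = 0.00089, adjusted p = 0.86 with an estimated correlation), with 1 of 41 called, the kinase PBK (-1.0, adjusted p = 0.049, 0.0523 with a pseudocount of 0.1), and 0 adjusted over the list alone (limma, 4 at an unadjusted p under 0.05). It did not pass with quantile normalization (-0.22, 0.066) or without H23 siNT replicate 1 (0.051), and its sign turned without H23 siKDM6B replicate 2 (0.19, 0.62). In all 907 genes differed, 758 higher and 149 lower, or 2565 with the replicate block within each line. With quantile normalization the split was 455 and 408 and with median ratios 504 and 316; the median change of all genes moved from 0.11 to -0.01 and 0.01. TRIB3 and MT1X (adjusted p = 0.019 and 0.020) did not pass without either DMSO library, H23 GSK-J4 replicate 2, either siNT library or H23 siKDM6B replicate 1 (0.0520 to 0.0888). PBK did not pass without either DMSO library, either GSK-J4 library, H23 siNT replicate 1 or H23 siKDM6B replicate 2 (0.126 to 0.199). The count was 378 without H23 DMSO replicate 1, 399 without H23 DMSO replicate 2, 469 without H23 GSK-J4 replicate 1, 392 without H23 GSK-J4 replicate 2, 387 without H23 siNT replicate 1 and 503 without H23 siKDM6B replicate 1.

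Called genes shared by compound and knockdown were few where few were called under siKDM6B, and their number depends on the fit. In A549, 1 gene was called lower in both, against 0.32 for independent lists (Fisher's exact test, two-sided, p = 0.29, Benjamini-Hochberg adjusted p = 0.50), with the library labelled A549 siKDM6B replicate 1 in the knockdown arm. In H23 limma called 0 shared genes in either direction, against 0.60 higher and 0.51 lower for independent lists, with 879 at an unadjusted p under 0.05 for the knockdown. With the knockdown fitted on its 4 H23 libraries alone, 119 of its calls were also higher and 165 also lower with GSK-J4 in H23, against 71.0 and 69.6 for independent lists (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 6.7e-11 and 9.9e-30), and 103 were called in opposite directions. With all 20 libraries in a joint fit, A549 and H23 together had 294 shared calls. The log2 changes correlated across genes, which are not independent replicates, at a Pearson r of 0.32 in A549 and 0.23 in H23. Of the 730 genes called lower in H23 and A549 under GSK-J4, 84.7% had a negative change under siKDM6B in H23 and 78.4% in A549. Of the 1520 called higher, 60.2% and 66.6% had a positive change. The median change of all tested genes under siKDM6B was -0.028 in H23 and 0.017 in A549. The shares of all tested genes with a negative or positive change were not counted.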

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

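Chosen only after the result was seen were the tests of replicate spread and of exchanged libraries in HCC827, of floor values, of NUP43, of the library labelled A549 siKDM6B replicate 1 and of H23 alone.

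The results of this part stand out because a test of the difference between cell lines passed its threshold. GSK-J4 acted otherwise in H23 than in HCC827 on 3183 genes by limma (576 with all 20 libraries in a joint fit and 2112 without HCC827 DMSO replicate 1). The ATF4 list differed by a median log2 value of 1.21, the hypoxia list by 0.97, the mitosis list by -0.88 and the histone list by 1.56, and with an estimated correlation none passed (camera adjusted p = 0.14, 0.12, 0.22 and 0.059). Among genes, SESN2 differed by 3.86, TRIB3 by 3.23, DDIT3 by 3.04, STC2 by 2.77 and TSC22D3 by 2.65, and CYP1B1 by -2.92, CDH1 by -2.22, PSMB9 by -1.85, UCP2 by -1.82 and the readthrough TGIF2-C20orf24 by -1.81.

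A549 and HCC827 differed on 1464 genes (67 with all 20 libraries in a joint fit, 616 without HCC827 DMSO replicate 1, 903 without HCC827 DMSO replicate 2, 975 without HCC827 GSK-J4 replicate 1, 909 without A549 DMSO replicate 1, 658 without A549 DMSO replicate 2 and 749 without A549 GSK-J4 replicate 2). The ATF4 list differed by 0.99, the mitosis list by -0.90 and the p53 list by 0.68; with an estimated correlation the p53 list alone passed (camera adjusted p = 0.048, against 0.12 for the ATF4 and mitosis lists). BEX2 differed by 4.07, FAM129A by 3.35, CSTA by 3.11 and MT1F by 2.49, and DMC1 by -2.25, FGB by -2.16, TGIF2-C20orf24 by -1.98 and C11orf86 by -1.84. FGB, FAM129A and CSTA were at or near the floor in HCC827. The fitted difference of RPS10-NUDT3 (-2.12) comes from an arm at the floor of 0.1 RPKM, depends on the pseudocount and bounds no fold.

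Between H23 and A549 the effect of GSK-J4 differed on 1341 genes (154 with all 20 libraries in a joint fit, 635 without H23 DMSO replicate 1, 668 without H23 GSK-J4 replicate 2, 751 without A549 DMSO replicate 1 and 740 without A549 DMSO replicate 2). The hypoxia list differed by 1.23, the histone list by 1.53, the cholesterol list by 0.53 and the glycolysis list by 0.51. With an estimated correlation the hypoxia and histone lists passed (camera adjusted p = 0.015 and 0.012) and the cholesterol and glycolysis lists did not (0.28 for both). SLC2A3 differed by 3.17, ANKRD37 by 3.02, IGFBP3 by 2.98, MYO10 by 2.52 and DHRS2 by 2.45, and CYP1B1 by -3.30, S100P by -2.73, NUPR1 by -2.40, CDH1 by -2.20 and PLAU by -2.08. S100P and NUPR1 were at or near the floor in H23. The effect of siKDM6B differed between H23 and A549 on 2 genes by limma (265 at an unadjusted p under 0.05; 19 with all 20 libraries in a joint fit, 9 without the library labelled A549 siKDM6B replicate 1, 10 without A549 siKDM6B replicate 2, 4 without A549 siNT replicate 1 or H23 siNT replicate 2, and 1 without H23 siKDM6B replicate 1 or replicate 2) and on the p53 list by -0.45, with 0 of 23 members called and a camera adjusted p of 0.97 with an estimated correlation. The fitted differences of HMGB1 (5.24) and EMC1 (4.05) rest on arms at the floor and bound no fold.

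Far fewer genes were called in HCC827 than in the other lines under GSK-J4. The median standard deviation within its groups was 1.04 times that of H23 and A549. The main fit shares a spread per gene over the lines, so a larger spread in HCC827 could not lower its count alone. Fitted on the 4 libraries of each line, limma called 0 genes in HCC827 (327 at an unadjusted p under 0.05), 5223 in H23 and 2376 in A549. For those fits, where each line has its own spread, a larger spread between HCC827 replicates is argued against. An exchange of a DMSO and a GSK-J4 library is argued against as well: the score of the genes called alike in H23 and A549 spanned 0.066 over the 4 HCC827 libraries, against arm differences of 1.05 in A549 and 1.23 in H23; this test was rewritten after an earlier version decided nothing. Still open is a smaller change of the same genes, since 58.1% of the genes called alike in H23 and A549 moved the same way in HCC827, between the bounds set for and against it. A line-specific response of HCC827 to GSK-J4, or treatment that did not reach the cells alike, may account for it and was not tested.

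The genes called under siKDM6B were mostly genes absent from an arm. Values at the floor for a whole group may be the cause for 7 of 8: 87.5% of the 8 genes called in any siKDM6B comparison had an arm of a line wholly at 0.1 RPKM while the same line under DMSO averaged at least 1 RPKM. Single siRNA libraries held such values too. HSPE1 read 0.1 in the library labelled A549 siKDM6B replicate 1, 258 in replicate 2 and 183 and 195 in A549 siNT. Genes at the floor in single libraries only were not counted and stay in the test without genes at the floor. What sets those values to the floor (the authors' processing, or a difference between annotations or batches) cannot be read from the table. For NUP43, the exception, the mean change under GSK-J4 in A549 and H23 was 0.047. Under siKDM6B it was -1.30, with the library labelled A549 siKDM6B replicate 1 in that arm. GSK-J4 thus did not lower NUP43. Demethylase activity was not measured and KDM6B mRNA rose under GSK-J4 in both lines, so this cannot decide on an effect of losing KDM6 activity. An effect of the siRNA on NUP43 itself or of the KDM6B protein apart from its catalysis stays open and was not tested.

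Replication and mitosis genes were lower under siKDM6B. A trend of the libraries with GC content and transcript length is argued against as the whole cause, since the median of the mitosis list over both lines stayed at -0.67 after its removal. The library labelled A549 siKDM6B replicate 1 is argued against too, as the median without it was -0.85. A difference of the A549 libraries alone is argued against less firmly: the median in H23 was -0.68, but -0.35 without H23 siKDM6B replicate 1, between the bounds set for and against it. A slower cell cycle after KDM6B knockdown may be a biological explanation, and it stays a hypothesis because the list had an adjusted p = 0.81 by camera with an estimated correlation, and cell density or toxicity of transfection was not measured.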

How the results depend on the processing

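Chosen only after the result was seen were the tests without genes at the floor, with the replicate block within each line and with that block and GC and length removal, and the list tests with median ratios. Counts of called genes are by limma, and for a changed count the cause was not tested unless named. With all 20 libraries in a joint fit the counts were 2126 for GSK-J4 in H23, 753 in A549, 1761 over the 3 lines, 576 for H23 against HCC827, 67 for A549 against HCC827 and 154 for H23 against A549. For siKDM6B that fit gave 579 in A549, 632 in H23, 1517 over both lines and 19 for the difference between lines, 294 overlaps with GSK-J4, and KDM6B at -0.51, now past the threshold (adjusted p = 0.0237). The joint fit pools groups of unequal spread, so its p-values may be too small where A549 siRNA libraries enter. With only the 4 libraries of a comparison the counts were 0 in HCC827 (327 at an unadjusted p under 0.05), 2376 for GSK-J4 in A549, 1 for siKDM6B in A549, 646 for siKDM6B in H23 and 284 overlaps. An additive fit gave 2456 for GSK-J4 and 3 for siKDM6B over the lines. A replicate block gave 6 in HCC827, 2 for siKDM6B in A549, 2523 for A549 against HCC827 and 2331 for H23 against A549; for the genes and lists given with values, it changed no other call than those stated beside them. The block within each line gave 11 in HCC827, 395 for siKDM6B over both lines, 4 for its difference between lines, 4788, 2992 and 2821 for H23 against HCC827, A549 against HCC827 and H23 against A549, and 1113 in A549 and 2565 in H23 for GSK-J4 against siKDM6B. For GSK-J4 that block gave 6475 in H23, 5081 in A549 and 6384 over the 3 lines. A pseudocount of 0.1 gave 8 for siKDM6B in H23, 4 for the difference between lines and 2 overlaps, and no filter gave 3 for siKDM6B in H23. Quantile normalization gave 14 and median ratios 12 for siKDM6B over both lines, and quantile normalization 3 overlaps. Without genes at the floor, which removes 7 of the 8 called genes and leaves NUP43 (adjusted p = 0.11 over both lines), siKDM6B had 0 calls in A549 (890 at an unadjusted p under 0.05), 0 in H23 (860), 0 over both lines (1454), 0 for the difference (253) and 0 overlaps; a change of at least 1 on the log2 scale gave 0 overlaps. Of 76 list calls in the 7 comparisons with controls, camera with an estimated correlation kept 2 and fry 36, and they called 2 and 48 lists in those comparisons; quantile normalization kept 68, median ratios 74, a pseudocount of 0.1 71, the replicate block 74, and leaving out libraries 398 of 472, with 0 in the opposite direction in these settings. Left-out libraries moved the counts from 4296 to 5112 for GSK-J4 over the lines, 3923 to 4196 in H23, 1888 to 3397 in A549 and 0 to 2 in HCC827. The ranges were 2112 to 2919 for H23 against HCC827, 616 to 1787 for A549 against HCC827 and 635 to 1316 for H23 against A549. For siKDM6B they were 4 to 147 in A549, 1 to 7 in H23, 4 to 857 over both lines (857 without the library labelled A549 siKDM6B replicate 1) and 1 to 10 for the difference, with KDM6B from -0.70 to -0.33. For GSK-J4 against siKDM6B they were 67 to 1523 in A549 and 378 to 642 in H23. The mitosis list reversed for GSK-J4 against siKDM6B. In A549 its median ran from -0.49 to 0.040, the latter without the library labelled A549 siKDM6B replicate 1. In H23 it ran from -0.47 to 0.19, the latter without H23 siKDM6B replicate 2. For named genes 9254 values kept direction and call, 262 passed anew and 521 no longer passed; for lists 688 kept both, 7 passed anew, 71 no longer passed and 2 reversed. Depth is unknown, so no limit from counting can be given.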

Other observations

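Chosen only after their values were seen were the genes of the next paragraphs; the counts of splits were chosen before.

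In A549, which alone of the 3 lines expressed fibrinogen, all 3 chains fell under GSK-J4: FGG by a log2 change of -1.22 (limma adjusted p = 1.3e-05), beside FGA (-1.75) and FGB (-2.18). FGA stood at 0.1 RPKM in the DMSO libraries of HCC827 and H23. Genes of antigen processing moved apart between lines. In H23 the immunoproteasome subunits PSMB9, PSMB8 and PSMB10 fell by changes of -1.62, -0.94 and -0.58 and the peptide transporter TAP1 by -0.86. In A549 PSMB8 rose by 0.59, and the difference between the lines was -1.53 for PSMB8 (limma adjusted p = 1.3e-05), -1.17 for TAP1 (adjusted p = 0.0011) and -0.59 for PSMB10 (adjusted p = 0.078, not past the threshold).

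For GSK-J4 over the 3 lines, 2 of 100 drawn splits of the libraries within lines called as many genes as the real split, itself included. That share is under 0.05, but the libraries of a group may hold technical variation only, so chance is not excluded. The real split called 5002 genes and the highest other 5329. That other split keeps the real arms of H23 and A549 and exchanges libraries of HCC827 alone, so the counts do not speak for HCC827. The 3 other splits that divide H23 and A549 as labelled in the same direction called 4803 to 5329 genes, the 6 with the direction of either line turned called 380 to 1419, and the remaining 90 at most 189. Among the 30 splits that part every replicate pair, the highest other called 4837. For siKDM6B over both lines, 8 of 18 splits called as many genes as the real split. These splits are too few for a share under 0.05; the real split called 6 genes and the highest other 140, several times the real count, which points to a structure of the samples. The splits with 126 and 140 calls divide H23 as labelled and A549 by replicate number, whose control and treated libraries deviated together (r = 0.60). The real split called 6 genes with a replicate block and 395 with the block within each line. Splits that do not divide H23 as labelled called at most 25. Among the 8 splits that part every replicate pair, the highest other called 5.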
